A study of Rattus norvegicus with 6 samples.

How the data were processed

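Gene expression was measured in the hypothalamus of Buffalo rats with 6 Agilent whole rat genome arrays, each reading 2 dyes. Per the labels, cDNA of 5 to 8 animals was mixed into 1 pool per group. The 3 pools came from tumor-bearing rats, from food-restricted rats of matched body weight and from freely feeding rats. Amplified RNA (aRNA) of one pool was coupled to Cy3 and that of another to Cy5, with 0.75 µg per dye. Each of the 3 pairs of pools was hybridised to 2 arrays, the second with the dyes swapped, so that the 6 arrays closed a loop. The labels name replicates only as arrays. Both arrays of a pair hold the same 2 pools, so their spread is technical and says nothing about the spread between animals.

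The scanner files were made by the authors with Agilent Feature Extraction A.7.5.1, with spatial detrending on and global background correction off. Per the file headers, the mean signals and local backgrounds of both dyes are in intensity units and were not normalised. The processed signals, also intensity per the file headers, had been reduced by a spatial background and normalised between dyes by the scanner software. The deposited ratio of each spot is the log10 of the Cy5 over the Cy3 processed signal. The deposited series table holds the same log10 ratios, with a largest difference of 0 from the scanner files, and is not turned for the dye swap. Its column medians lay between -0.00291 and 0.00388. No genome build applies to these values.

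Probes were named through a table of RefSeq genes of the rat assembly GRCr8, used for names only, by transcript, gene identifier, symbol or older symbol. Of 41012 different probes, 18527 were matched and the other 22485 kept the name in the files. A gene symbol was available for 18581 probes, which stand for 15995 different genes.

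The ratios were computed from the mean signals and median local backgrounds in R 4.3.3 with limma 3.58.1, and the files were read with data.table, version 1.17.8. Background was corrected by normexp with an offset of 50, and each array was normalised by loess with control spots at weight 0. The offset pulls log2 ratios toward 0, most at dim probes. Log2 ratios were turned to the first-named over the second-named pool and averaged over the 2 arrays of a comparison. Probes that the scanner software marked as non-uniform or as population outliers in either dye on any of the 6 arrays were left out, 14655 probes or 35.7%. The other 26357 probes stood for 24964 genes. A gene was tested in a comparison where its probe was well above background on both arrays in at least 1 of the 2 pools, and the brightest remaining probe represented the gene.

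The groups have 1 pool each, so no test between groups and no p-value is possible, and none is given. A gene was taken to rise or fall by a size rule with 3 parts. The mean log2 ratio had to reach log2 of 1.5 (0.585) in either direction, both arrays had to have the same sign, and so did the ratio through the third pool, which comes from the other 4 arrays. In tumor-bearing versus freely feeding that ratio also holds the array component described with the results. Each value is given with a technical standard error from a limma fit of the loop with a dye term, moderated across genes (3 residual degrees of freedom, median prior degrees of freedom 6.10, median technical SD 0.123). This error covers the scatter between arrays and dyes only, with the arrays taken as independent. The array component that arrays of one dye orientation share is not fully covered by it. The size rule was also run on 100 simulated sets with no difference between pools and the technical spread of each gene. Those sets do not hold the array component described with the results. The overlap of genes between comparisons was set beside 100 simulated sets of 3 independent pools, with deviations drawn from the observed ratios, divided by the square root of 2 and given a random sign. That simulation was added after the overlap had been seen and applied the 1.5-fold limit to the ratio only. The procedure was tested on simulated data with 200 changed genes. In tumor-bearing versus freely feeding it recovered 43.5% of the genes made 1.5-fold different (20 of 46), and in tumor-bearing versus food-restricted 57.4% (27 of 47). All genes made 2-, 3- or 4-fold different were recovered in these 2 comparisons. The genes made 2-fold different had median log2 estimates of 0.98 and 1.02 in size, so they were not pulled toward 0. The offset does pull measured ratios toward 0, most at dim probes. The recovered shares therefore do not show how many real changes of these sizes would pass the rule.

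Gene lists were summarised by the median log2 ratio of their tested members and by its percentile among 10000 random lists of the same size matched on intensity in 20 bins. A list was set apart when the percentile lay outside the central 95%. There were 31 lists: feeding peptides and receptors, hormones and releasing factors, prostaglandins, inflammation and interferon response, immediate early and glucocorticoid-responsive genes, heat shock, cholesterol synthesis and fuel metabolism, the circadian clock, synaptic and monoamine genes, hypothalamic transcription factors, oxidative phosphorylation, ribosomal proteins, and the core feeding genes. The rest were markers of other cells or regions: oligodendrocytes, astrocytes, tanycytes, microglia, choroid plexus, vessels, meninges, blood, anterior pituitary, thalamus, striatum and cortex, liver and hepatoma. The ribosomal list takes every symbol of the family pattern, pseudogenes included.

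Genes are named by a rule. It takes the 10 highest and the 10 lowest ratios among genes past the size rule that carry a symbol, the core feeding genes whatever their value, and up to 4 genes past the size rule in each list. For genes named singly, no ratio is given where a pool was saturated on an array of the comparison. A further gene that the rule takes is not reported here; it stays in the counts and list medians. The size rule, the lists, the naming rule and most of the alternative settings were fixed before the data were examined. Genes named only to describe a list, the comparison with other probes of a gene and the comparison with the parent genes of pseudogenes were chosen after the values were seen.

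The alternatives fixed in advance were no background subtraction, the processed signals with loess, a normexp offset of 16, median centring, the deposited ratios, Aquantile scaling between arrays, no filter or a stricter filter on background, saturated probes left out, the mean over the probes of a gene, a least-squares estimate over the loop, the same with the slide series as a block (3 arrays in each series), no requirement on the third pool, a further requirement of 3 technical standard errors, thresholds of 2-fold and 1.3-fold, and each array of a comparison left out in turn. After the data had been seen, runs were added with the marked spots kept, with the dye effect of each probe removed, with the shared array component removed, and with pseudogenes left out of the family lists. Removal of the shared array component takes it to be of equal size in the 3 comparisons, which was not tested. The resulting ratios combine more than 1 comparison, so they carry more technical error than the direct ratios, most of all in tumor-bearing versus freely feeding. They are given without an error. Leaving out replicate 2 of tumor-bearing versus freely feeding, already among the fixed runs, also served as the run without the array with the most marked spots. With an array left out, the dye effect of each probe is not cancelled in that comparison and the same-sign part of the rule does not apply. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the rules, lists and plots.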

Results

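The hypothalamus, the brain region that governs feeding, was profiled in Buffalo rats of 160 to 230 g. Tumor-bearing rats had received 10000000 cells of Morris hepatoma 7777, a transplantable rat liver tumor, under the skin between the shoulder blades and ate freely. Freely feeding controls had received saline. When the gain in body weight of these groups had come to differ by 10%, 8 further rats were held to a 33% food restriction until they matched the tumor-bearing rats in weight. Each group was measured as 1 pool of cDNA, and each pair of pools on 2 arrays with the dyes swapped. There are no biological replicates, so each value is the mean of 2 arrays with its technical standard error, and a difference between pools cannot be separated from a difference between the animals that happened to be in them.

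Each array carried 43628 spots, 41372 of them for genes. Between 97.36% and 98.53% of the probes were well above background in Cy3 and between 92.65% and 95.09% in Cy5. Median mean signals were 555 to 955 intensity units in Cy3 and 352 to 487 in Cy5, over backgrounds of 37 to 43 and 63.5 to 67. Between 25 and 125 spots per dye were saturated. The scanner software marked 2.66% to 15.9% of the spots as uneven or outlying, with the highest share on replicate 2 of tumor-bearing versus freely feeding. The number of arrays limits the precision.

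Food-restricted versus freely feeding rats contrast eating less with eating freely, without a tumor and with 1 pool each. Of 23507 genes tested, 5 rose in the food-restricted pool and 0 fell. Npm1-ps1, a processed copy of the nucleophosmin gene (LOC364556 in the files), rose by 0.80 ± 0.19 on the log2 scale, 1.75-fold, and Rpl3-ps5, a copy of a ribosomal protein gene (LOC302564 in the files), by 0.59 ± 0.20. The other three have no symbol, and are named because the count is small, after their values were seen: LOC366433 at 0.70 ± 0.13, LOC299251 at 0.70 ± 0.16 and LOC301792 at 0.61 ± 0.18. All 5 also rose in tumor-bearing over freely feeding rats, a comparison that shares the freely feeding pool. With the shared array component removed, Npm1-ps1 read 0.47 and Rpl3-ps5 0.46 there, short of 1.5-fold.

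The simulated sets without any difference gave 1.02 such genes on average and at most 4. The count was 0 with the slide series as a block and 91 from the processed signals, and single arrays gave 348 without replicate 1 and 491 without replicate 2. Some larger counts went both ways, with 58 higher and 33 lower from the processed signals, 34 and 15 from the deposited ratios and 39 and 21 at 1.3-fold. Replicate 2 carried little of the named rises, with 0.15 for Npm1-ps1 against 1.46 on replicate 1, and 0.04 for Rpl3-ps5 against 1.15. With the shared array component removed, Npm1-ps1 read 0.43 and Rpl3-ps5 0.36, and 0 of the 5 genes stayed past the rule. The parent gene Npm1 read -0.04 ± 0.09 with its own probe. Rpl3 read -0.06 with marked spots kept.

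Among the core feeding genes, 10 of 14 could be tested and 0 passed the rule in food-restricted versus freely feeding rats. Npy, which drives feeding, read -0.12 ± 0.14, Pomc, the source of the satiety peptide of the arcuate nucleus, read -0.08 ± 0.23, and the orexin gene Hcrt read 0.18 ± 0.14. The leptin receptor Lepr read 0.15 ± 0.12 and the ghrelin receptor Ghsr -0.22 ± 0.11. Trh, Oxt, Avp and Ptgds lay between -0.08 and 0.10, and Pmch was saturated in each pool on 1 array and cannot be judged. Agrp had no matched probe, and the probes of Cartpt, Mc4r and Crh were marked on at least 1 array, so these 4 genes were not analysed here. The 2 arrays could differ in sign, as for Hcrt with -0.44 and 0.79, and so could the routes, with -0.28 for Hcrt, -0.33 for Avp and 0.14 for Ghsr through the third pool.

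Astrocyte markers stood apart as a group in food-restricted over freely feeding rats, although 0 of 9 tested members passed the rule. Their median was 0.17, the 99.98th percentile of random lists, and 8 of 9 lay above 0. Gfap, the astrocyte filament, read 0.31 ± 0.08, Fabp7, a fatty-acid binding protein, 0.23 ± 0.08, the gap junction gene Gja1 0.17 ± 0.11, and the glutamate transporter Slc1a2 -0.11 ± 0.09. Ribosomal protein genes had a median of 0.008 (percentile 99.35), with 1 of 125, Rpl3-ps5, past the rule and 71 above 0. Through the third pool the astrocyte median was 0.10 (percentile 97.18) and the ribosomal median -0.02 (percentile 37.55), so neither list was outside the central 95% by both routes. Over 17 settings, single arrays not among them, the astrocyte median ranged from 0.02 to 0.18 and lay outside the central 95% in 15. Of 31 lists, these 2 were outside it, where chance gives 1.55.

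**Figure D1:**
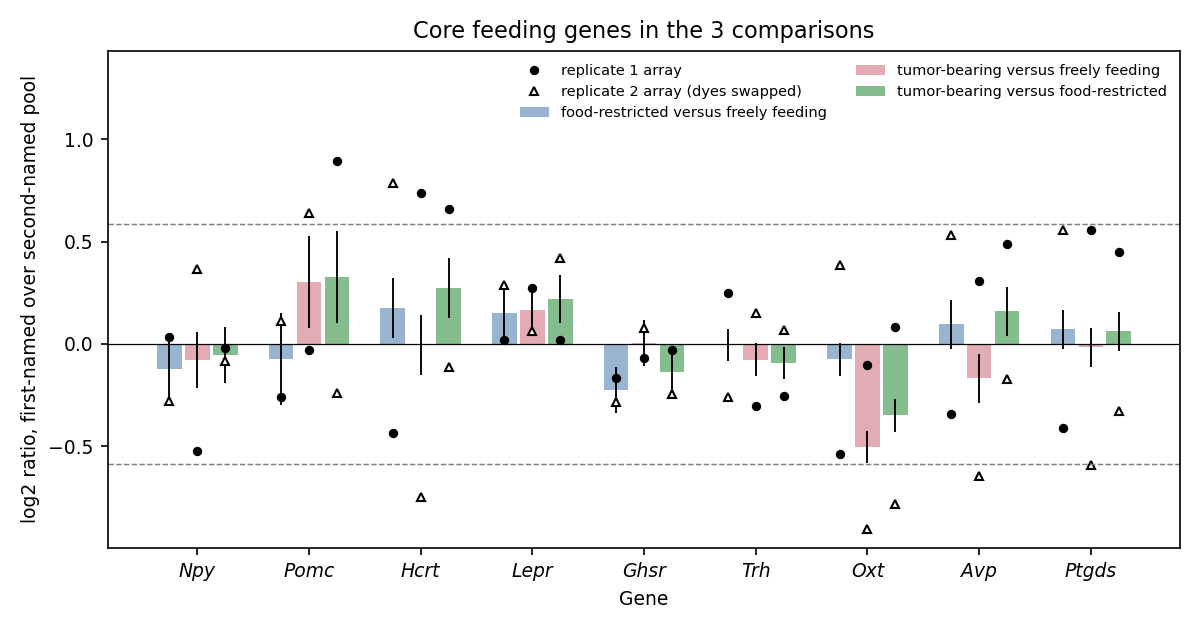
Log2 ratios of the core feeding genes (y axis) per gene (x axis) in the 3 comparisons. Bars are means of 2 arrays, error bars technical standard errors, circles and triangles the arrays, and dashed lines mark 1.5-fold. No bar reaches a dashed line, and Oxt in tumor-bearing versus freely feeding comes nearest at -0.51. Pmch is not drawn because it was saturated.

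Tumor-bearing versus freely feeding rats contrast pools that differ in the tumor together with the lower weight gain that came with it. Of 22916 genes tested, 131 rose and 16 fell in the tumor-bearing pool. The receptor genes Gpr6 (0.94 ± 0.09, 1.92-fold), Drd1 (0.70 ± 0.08, 1.62-fold) and Adora2a (0.59 ± 0.14) rose. Drd1 and Adora2a, which encode a dopamine and an adenosine receptor, are in the list of striatum and cortex markers. Inpp5f, an inositol phosphatase, rose by 0.87 ± 0.15, Zc4h2, a zinc finger gene, by 0.80 ± 0.17, and Sphkap, an anchor of protein kinase A, by 0.85 ± 0.12 with the freely feeding pool above background on 1 of 2 arrays. The genes that fell included Akap12, a scaffold for protein kinase A, at -1.04 ± 0.11 (2.06-fold), and Gad1, which makes GABA, at -0.65 ± 0.14.

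The simulated sets gave 1.16 genes on average and at most 5. The count was 68 without background subtraction and 744 from the processed signals, and single arrays gave 879 without replicate 1 and 598 without replicate 2. Of the 131 genes that rose, 48 have a symbol and 15 of these are pseudogenes or copies of another gene. Among genes with a symbol, such copies hold the highest pair of values and others further down: Hspa8-ps34 (1.22 ± 0.18), Ptges3l1 (1.003 ± 0.13), Hspa8-ps6 (0.88 ± 0.21), Rpl37al2 (0.87 ± 0.18), Rps16-ps2 (0.85 ± 0.14) and Npm1-ps1 (0.85 ± 0.19). The parent genes read -0.08 ± 0.09 for the heat shock gene Hspa8 and 0.11 ± 0.09 for Npm1. Rps16 was saturated in 1 of the pools on each of the 2 arrays and cannot be judged. With marked spots kept, Ptges3 read 0.15 and Rpl37a -0.24.

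Of the 16 genes that fell, 6 had a brighter probe lost to outlier marks, and in 4 of these the brighter probe had the opposite sign. That probe read 0.19 for Akap12, 0.21 for Gad1, 0.12 for Ppp3r1, the calcineurin regulatory subunit, and 0.34 for Map1b, a microtubule protein, against -0.95 ± 0.39 and -0.79 ± 0.31 for the probes of Ppp3r1 and Map1b that were used. These 4 falls therefore hold for dimmer probes only. Other unmarked probes read -0.89 and 0.21 for Map1b and -0.27 for Gad1. Other genes that fell were Cpsf7, a pre-mRNA cleavage factor (-0.68 ± 0.12), Tmem150c (-0.68 ± 0.13), L3mbtl2 (-0.64 ± 0.08), the semaphorin receptor Plxnb2 (-0.63 ± 0.09), Cd2bp2 (-0.62 ± 0.09) and Gnrhr, the receptor of gonadotropin-releasing hormone (-0.63 ± 0.20), whose other 2 probes read 0.45 (marked) and -0.09.

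Of the markers of striatum and cortex, 3 of 7 tested members rose in tumor-bearing over freely feeding rats and 0 fell. The median was 0.41, the 100th percentile of random lists, and 0.45 through the third pool, also the 100th. Rgs9, a brake on G protein signals in striatal neurons, read 0.41 ± 0.09, and the striatal phosphatase inhibitor Ppp1r1b 0.08 ± 0.11. The cortical genes Neurod2 and Slc17a7 read -0.05 ± 0.08 and -0.30 ± 0.07. A brighter, marked probe of Adora2a read 0.31. With the shared array component removed Adora2a read -0.02 and so did the list median, at percentile 50.78, and without replicate 2 Drd1 read 0.46.

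Feeding genes in tumor-bearing versus freely feeding rats gave 0 past the rule among the 10 core genes. Oxt, the oxytocin gene, read -0.51 ± 0.08, with -0.10 and -0.91 on the arrays and -0.43 through the third pool, short of 1.5-fold. Pomc read 0.30 ± 0.23, Npy -0.08 ± 0.14, Hcrt -0.01 ± 0.14, Lepr 0.17 ± 0.12, Avp -0.17 ± 0.12, and Ghsr, Trh and Ptgds lay between -0.08 and 0.004. Through the third pool Hcrt read 0.45, Avp 0.25 and Ghsr -0.36, and the other Avp probe read -0.37 directly. Pmch was saturated in the freely feeding pool on both arrays and cannot be judged. The wider list of orexigenic peptides had a median of 0.19 (percentile 99.04, 7 tested with the saturated Pmch among them, 0 past the rule), with Penk at 0.31 ± 0.09, Npvf at 0.27 ± 0.09 and Galp at 0.19 ± 0.10. Through the third pool the list lay at the edge of the central 95%, not outside it. The median ranged from 0.11 to 0.30 over 17 settings and lay outside the central 95% in 12 of them, not among them the run with marked spots kept. Penk is also abundant in striatal neurons, and the markers of striatum and cortex had a median of 0.41 in this comparison.

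Genes of protein synthesis and respiration also stood apart as lists in tumor-bearing over freely feeding rats, by small amounts. Ribosomal protein genes had a median of 0.05 (percentile 100; 99.94 through the third pool), with 67 of 123 above 0. The 4 that rose were copies, Rpl37al2, Rps16-ps2, Rpl36Al2 (0.71 ± 0.15) and Rpl3-ps5 (0.69 ± 0.20). Oxidative phosphorylation genes had a median of 0.02 (percentile 97.67, but 97.37 through the third pool; 30 of 56 above 0), and Sdhaf2, an assembly factor of succinate dehydrogenase, rose by 0.63 ± 0.13, while its brighter, marked probe read 0.12. The oxidative phosphorylation list lay outside the central 95% in 9 of 17 settings. In all, 4 of 31 lists were outside the central 95%, where chance gives 1.55, and 2 of them by both routes, striatum and cortex and ribosomal proteins. Both routes hold the shared array component in this comparison, so their agreement does not set it aside. With it removed, striatum and cortex lay at percentile 50.78 and ribosomal proteins at 81.5. Without replicate 2 the oxidative phosphorylation median was -0.05 and without replicate 1 the ribosomal median was -0.04.

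**Figure D2:**
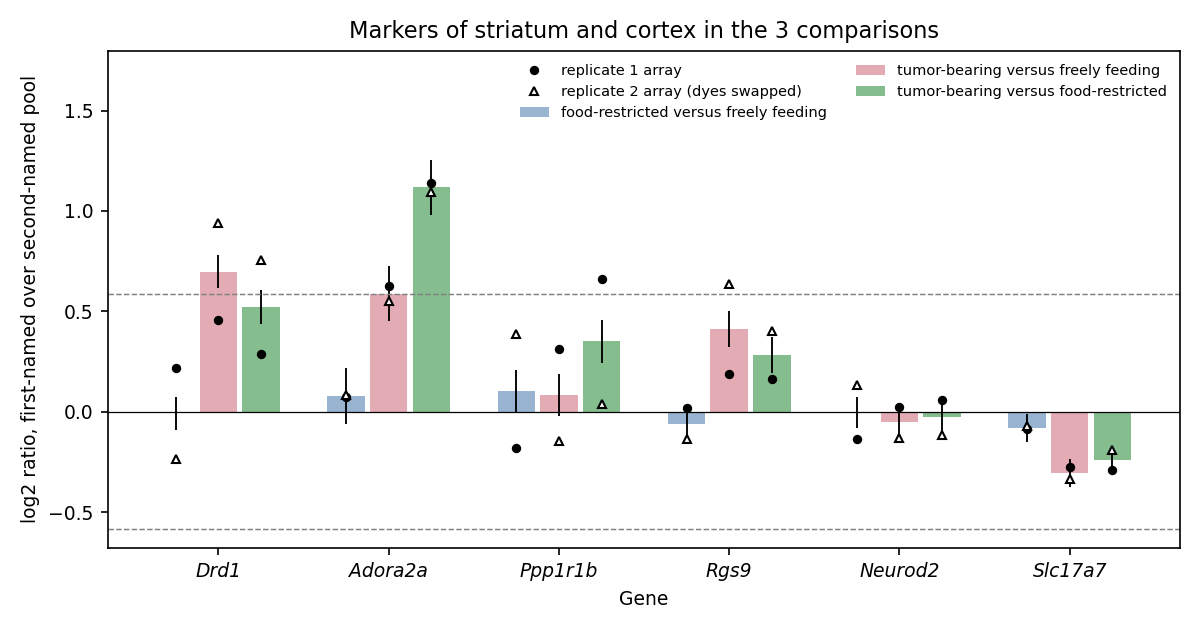
Log2 ratios of 6 tested markers of striatum and cortex (y axis) per gene (x axis) in the 3 comparisons. Bars are means of 2 arrays, error bars technical standard errors, circles and triangles the arrays, and dashed lines mark 1.5-fold. Drd1 and Adora2a stand above 0 on both arrays of both tumor-bearing comparisons, while Neurod2 and Slc17a7 do not.

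Tumor-bearing versus food-restricted rats contrast the tumor with food restriction at matched body weight. Of 23323 genes tested, 14 rose and 5 fell in the tumor-bearing pool. Adora2a rose by 1.12 ± 0.14 (2.17-fold), Bcl11b, a transcription factor of striatal neurons, by 0.76 ± 0.10, and Ulk1, a kinase that starts autophagy, by 0.67 ± 0.19. Inpp5f rose by 0.62 ± 0.15 and Chp1, a calcium-binding protein, by 0.61 ± 0.19. Akap12 fell to -0.98 ± 0.11 and Gad1 to -0.81 ± 0.14.

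The simulated sets gave 0.96 genes on average and at most 4. The count was 9 without background subtraction and 102 from the processed signals. Single arrays gave 517 without replicate 1 (469 higher, 48 lower) and 64 without replicate 2 (18 higher, 46 lower). The prevailing direction thus differed between the arrays. A single array leaves the dye effect of each probe in the ratio and skips the same-sign part of the rule, so these counts do not compare directly with the main ones. Brighter probes, marked only on arrays of other comparisons, read 0.0009 for Akap12, 0.10 for Gad1, 0.46 for Adora2a and 0.22 for Chp1, so the falls of Akap12 and Gad1 hold for the dimmer probe only. Through the third pool, a shared array component of equal size in the comparisons drops out. By that route Adora2a read 0.51, Bcl11b 0.38 and Ulk1 0.37, each short of 1.5-fold, while Inpp5f read 0.60, Chp1 0.59, Akap12 -1.10 and Gad1 -0.83. Inpp5f and Chp1 read 0.07 and 0.14 on replicate 1 against 1.16 and 1.08 on replicate 2.

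The markers of striatum and cortex had a median of 0.35 in tumor-bearing over food-restricted rats, the 100th percentile, with 2 of 7 past the rule, and 0.47 through the third pool, also the 100th. Drd1 read 0.52 ± 0.08, Rgs9 0.28 ± 0.09 and Ppp1r1b 0.35 ± 0.11, while Neurod2 and Slc17a7 read -0.03 ± 0.08 and -0.24 ± 0.07. In food-restricted versus freely feeding rats the same list had a median of -0.01 (percentile 48.1). Meningeal markers had a median of 0.13 (percentile 98.99, 8 tested, 0 past the rule) but -0.08 through the third pool.

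Core feeding genes again gave 0 of 10 past the rule in tumor-bearing versus food-restricted rats. Oxt read -0.35 ± 0.08 (0.08 and -0.78 on the arrays), Pomc 0.33 ± 0.23, Hcrt 0.27 ± 0.14, Lepr 0.22 ± 0.12, Avp 0.16 ± 0.12, Ghsr -0.14 ± 0.11, Trh -0.09 ± 0.08, Npy -0.05 ± 0.14 and Ptgds 0.06 ± 0.10, and Pmch, saturated in each pool on 1 array, cannot be judged. Through the third pool Avp read -0.26, Hcrt -0.18 and Ghsr 0.23, opposite to these values, and the other Avp probe read -0.33 directly. The orexigenic list, Pmch included, had a median of 0.14 (percentile 99.13), with Npvf at 0.22 ± 0.09 and Penk at 0.16 ± 0.09, but lay inside the central 95% through the third pool (percentile 93.21) and read -0.04 without replicate 1. Ribosomal protein genes had a median of 0.03 (percentile 100; 94.88 through the third pool), with 0 of 125 past the rule. In all, 4 of 31 lists were outside the central 95%, where chance gives 1.55, and 1 of them, striatum and cortex, by both routes.

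The question of whether the tumor-bearing pool differs from both others was put to the genes past the rule in both comparisons. In all, 10 genes rose over both, among them Adora2a, Inpp5f, Chp1 and 6 genes without a symbol, and Akap12, Gad1 and 2 genes without a symbol fell against both. Independent lists of these sizes would share 0.0805 and 0.00354 genes, but the comparisons share a pool. Simulated independent pools, with deviations drawn from the observed ratios, shared 4.21 genes on average (at most 12) and 4.25 (at most 9), with 38.8 and 39.2 genes past 1.5-fold per set in these comparisons against 147 and 19 observed. The simulated lists differ from the observed ones in size and direction and the independent lists leave out the shared pool, so whether the overlap exceeds chance is left open. Relative to freely feeding rats, 5 genes rose in both the food-restricted and the tumor-bearing pool, against 0.0288 for independent lists and 4.11 on average (at most 10) in the simulated pools, whose food-restricted lists held 38.3 genes instead of 5, and 0 fell. The 131 genes that rose in tumor-bearing over freely feeding rats had medians of 0.31 in food-restricted over freely feeding and 0.33 in tumor-bearing over food-restricted, while the 16 that fell had medians of 0.004 and -0.57.

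Across 22602 genes, which are not independent replicates, the ratios of the food-restricted and the tumor-bearing pool over the freely feeding pool correlated with r = 0.621, where simulated independent pools sharing a reference gave 0.5005 (covariance 0.0176 against 0.0130). It was 0.158 without replicate 1 of food-restricted versus freely feeding and 0.251 without replicate 1 of tumor-bearing versus freely feeding. Food-restricted over freely feeding and tumor-bearing over food-restricted, which share no array, correlated with r = 0.672, where the simulated pools gave -0.4995. Olfactory receptor genes, chosen after this was seen as a family of the nose, showed the same relation with r = 0.759 over 493 genes. The 2 arrays of a comparison, turned to the same direction, correlated with r = -0.41, -0.07 and -0.26 in the order food-restricted versus freely feeding, tumor-bearing versus freely feeding and tumor-bearing versus food-restricted. Direct ratios and ratios through the third pool correlated with r = 0.196, 0.717 and 0.241 in that order, and 58.2%, 79.1% and 55.7% of the genes had the same sign by both routes. In tumor-bearing versus freely feeding both routes hold the shared array component, so their agreement there does not set it aside.

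**Figure D3:**
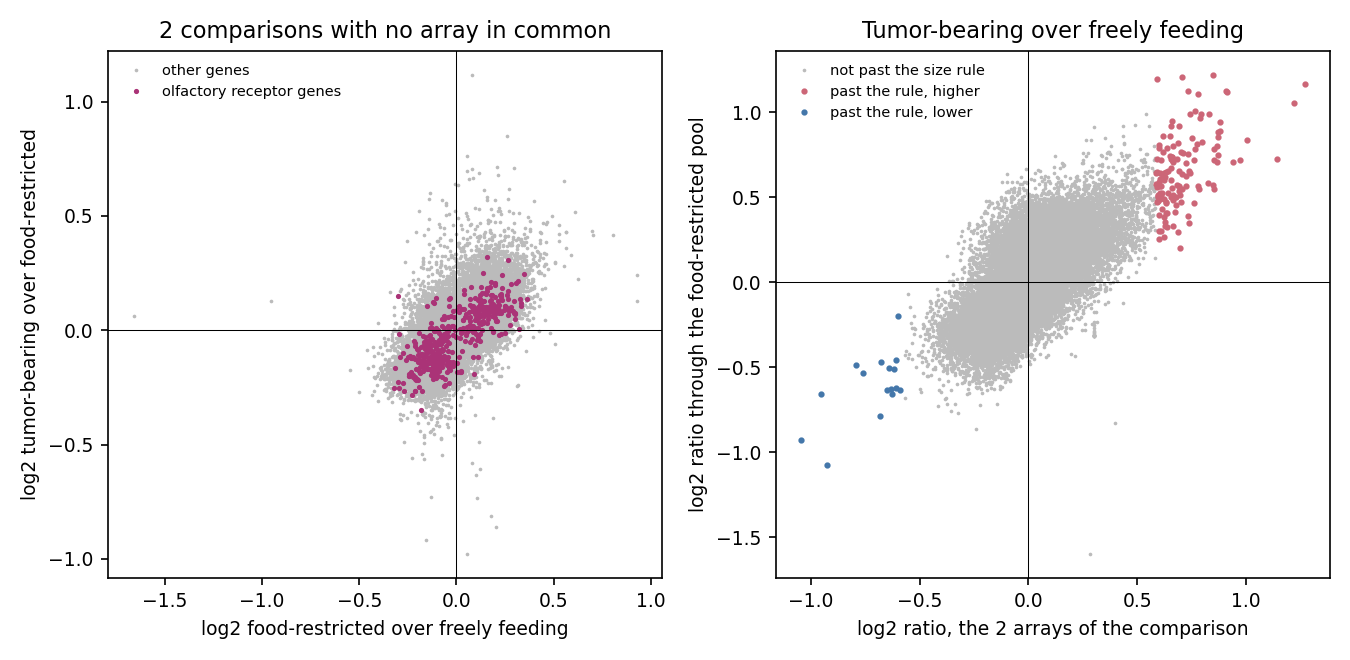
Each point is a gene. On the left, log2 food-restricted over freely feeding (x axis) is set against log2 tumor-bearing over food-restricted (y axis), with the 493 olfactory receptor genes in purple (r = 0.759). On the right, log2 tumor-bearing over freely feeding from its 2 arrays (x axis) is set against the ratio through the food-restricted pool (y axis), with the 131 genes that rose in red and the 16 that fell in blue (r = 0.717 across all tested genes).

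The remaining lists stayed inside the central 95% of random lists in all 3 comparisons by the direct route, and their medians follow in the order food-restricted versus freely feeding, tumor-bearing versus freely feeding, tumor-bearing versus food-restricted. Anorexigenic peptides read -0.08, -0.09 and -0.09, feeding receptors and signalling -0.02, -0.004 and -0.009, hormones and releasing factors 0.04, -0.08 and -0.05, and the core feeding genes -0.005, -0.01 and 0.03. Prostaglandin genes read -0.04, 0.008 and -0.08, cytokines and inflammation -0.04, -0.08 and -0.01, and interferon response and antigen presentation -0.02, -0.11 and -0.07. Immediate early genes read -0.06, -0.04 and -0.03, glucocorticoid-responsive genes -0.08, -0.12 and -0.07, and heat shock and unfolded protein genes -0.05, -0.06 and -0.009. Cholesterol synthesis read 0.01, -0.04 and 0.03, fuel metabolism -0.03, -0.04 and -0.03, and the circadian clock -0.01, -0.10 and -0.04. Synaptic transmission genes, where Gad1 was the member that fell, read 0.05, 0.05 and 0.02, monoamine genes 0.02, -0.04 and -0.02, and hypothalamic transcription factors 0.09, 0.07 and 0.02.

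Markers of other cells and regions behaved likewise in that order. Oligodendrocytes read -0.04, -0.10 and -0.08, tanycytes and ependyma -0.01, 0.04 and 0.06, microglia and macrophages -0.04, -0.12 and -0.03, choroid plexus -0.10, -0.13 and 0.02, and vascular cells 0.003, 0.02 and 0.006. Blood cells read -0.01, 0.06 and 0.04, the anterior pituitary -0.12, -0.09 and -0.11, the thalamus 0.06, 0.03 and 0.04, and liver and hepatoma 0.07, 0.03 and 0.002. Astrocyte markers read 0.06 (percentile 91.35) in tumor-bearing over freely feeding and 0.02 (80.23) in tumor-bearing over food-restricted rats, with Gfap at 0.48 ± 0.08 and 0.10 ± 0.08. Meningeal markers read -0.04 and -0.05 over freely feeding rats, in the food-restricted and tumor-bearing pools, orexigenic peptides 0.05 in food-restricted over freely feeding, and oxidative phosphorylation -0.007 in food-restricted over freely feeding and -0.005 in tumor-bearing over food-restricted.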

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

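The test of the second striatal list was set before its values were seen; the other tests of explanations in this part were chosen after the results were seen.

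Akap12 drew attention because both arrays of food-restricted and both arrays of tumor-bearing rats moved in opposite directions from freely feeding rats. Tumor-bearing over food-restricted, Akap12 read -0.98. Food-restricted over freely feeding it read 0.05 ± 0.11, less than its technical error. The difference between the groups was not tested, since each is 1 pool. The brighter probe of Akap12 read 0.0009 in that comparison.

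By the direct ratios, the median of the striatum and cortex list was higher in the tumor-bearing pool than in both others. The difference from food-restricted rats was set against the array component shared by one dye orientation. The third-pool route, in which a component of equal size in the comparisons drops out, put the list at the 100th percentile (median 0.47). The tables argue against such a component as the cause of that difference, while one of unequal size is not excluded. For the difference from freely feeding rats the component cannot be told apart. With it removed the list median lay at percentile 50.78, while Drd1 read 0.88 and Rgs9 0.60 and 4 of the 7 tested members lay below 0. A candidate explanation is that some striatal tissue was dissected with the hypothalamus of tumor-bearing rats: a second list of 19 tested striatal genes, in none of the other lists, had a third-pool median of 0.14 over food-restricted rats (percentile 99.99) with 13 of 19 above 0 by that route, among them Rasd2 at 0.53, Foxp1 at 0.34 and Scn4b at 0.33, though abundant striatal genes read less (Penk 0.26, Phactr1 0.17, Hpca 0.13, Gnal -0.11). Through the third pool the second list read -0.10 in food-restricted over freely feeding rats (percentile 1.11). Its direct median in tumor-bearing over freely feeding rats was 0.11 (percentile 99.14), but that ratio holds the component. More striatal tissue in the tumor-bearing pool is thus not told apart from less in the food-restricted pool. Cortical Neurod2 and Slc17a7 were not higher, and a change within the hypothalamus of tumor-bearing rats stays open and untested.

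The 3 comparisons share a component that independent pools would not give. Pools on one true axis with food-restricted rats in between would need a correlation of 2.91 between the steps of that axis (lower bootstrap limit 2.74), and a correlation has a ceiling of 1, so the axis alone is excluded. A signal of the arrays unrelated to hypothalamic transcripts is a candidate cause: olfactory receptor genes showed the relation with r = 0.759 (bootstrap interval 0.718 to 0.795) against 0.664 in other genes. Their probes were marked well above background in 94.6% to 99.4% of cases, so that mark does not show expression. As Cy5 over Cy3, before turning for the dye swap, arrays with the pools in the same dye orientation correlated with r = 0.55 to 0.75 over 6 pairs, and in opposite orientation with -0.29 to 0.52 over 9.

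More genes rose than fell in tumor-bearing versus freely feeding rats, 131 against 16. If the array component were the whole cause, genes at least 1.5-fold higher by the other 4 arrays would have a quotient of the direct ratio over the sum of the other comparisons of at most 0.5, and the median over 233 such genes was 0.651 (bootstrap interval 0.583 to 0.717). A first bound of 0.75 was replaced by 0.5 after the value had been seen, because the component enters that sum 2 times. The 57 genes lower by the same measure had a median of 0.444. A contribution of the component may remain, and a component of unequal size is not excluded as the whole cause. A difference between the pools, of tumor or of animals, stays open and untested.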

How the results depend on the processing

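No paired analysis was possible because each group is 1 pool. The runs with marked spots kept, with the dye effect or the shared component removed and without pseudogenes were chosen after seeing the data. Counts of genes past the size rule follow in the order food-restricted versus freely feeding, tumor-bearing versus freely feeding, tumor-bearing versus food-restricted, against 5, 147 and 19. They were 3, 68 and 9 without background subtraction, 91, 744 and 102 from processed signals with loess, 10, 264 and 38 with an offset of 16, 49, 694 and 86 from the deposited ratios and equally from the series table, 60, 936 and 135 at 1.3-fold, 0, 5 and 1 at 2-fold, 15, 299 and 32 with marked spots kept, and 13, 471 and 32 with the shared component removed. The first count was also 3 with the loop estimate, 0 with the slide series as a block and 8 with the dye effect removed. Single arrays gave 348 to 491, 598 to 879 and 64 to 517. The threshold explains the counts at 1.3-fold and 2-fold. Single arrays leave the dye effect of each probe in the ratio and skip the same-sign part of the rule. How much each of these adds was not tested. The offset of 50, added to both dyes, pulls log2 ratios toward 0, most at dim probes. It stands in the main run and in the run without background subtraction. The processed signals and deposited ratios have no such offset. How far this accounts for the counts was not tested, nor was the cause for the other settings. With the shared component removed, 0, 118 and 10 of the genes were shared with the counts above. Ratios with the component removed carry more technical error, which raises counts at a fixed limit by an amount that was not tested. The share that rose in tumor-bearing versus freely feeding, 89.1%, was 72.0% from processed signals and 75.5% from the deposited ratios.

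The correlations of direct and third-pool ratios were -0.0058, 0.571 and 0.112 with median centring, and ranged over single arrays from -0.217 to 0.470, 0.298 to 0.714 and -0.174 to 0.423. They cannot be had from the loop fits or with the component removed, whose ratios close exactly. The relation of both pools over freely feeding rats (0.621) was 0.473 with median centring, 0.868 with the loop estimate, 0.771 with the slide block and 0.915 with the component removed, where the ratios share arrays by construction, and 0.158 to 0.626 over single arrays. The number of lists outside the central 95% stayed between 7 and 11 over 17 settings. The striatum and cortex list was outside in 17 of 17 settings over food-restricted and 16 of 17 over freely feeding rats, ribosomal proteins in 14, 16 and 16 in the order above, and astrocytes in food-restricted versus freely feeding in 15. Orexigenic peptides were outside in 12 over freely feeding and 14 over food-restricted rats, meninges in 9 over food-restricted and oxidative phosphorylation in 9 over freely feeding rats. Single arrays are not among the 17 settings. Removal of the dye effect cannot change a list median, Aquantile scaling leaves the ratio of a probe as it was, and the series table repeats the deposited ratios. On single arrays ribosomal proteins lay inside the central 95% in both comparisons with freely feeding rats. The percentiles were 68.64 and 92.58 for the food-restricted pool and 93.9 and 94.24 for the tumor-bearing pool.

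Some signs reversed, and apart from the change of probe with marked spots kept the cause was not tested. With marked spots kept, Akap12 read 0.193, Ppp3r1 0.116, Map1b 0.344 and Gad1 0.206 in tumor-bearing versus freely feeding, and Akap12 0.0009 and Gad1 0.097 in tumor-bearing versus food-restricted. With the component removed, Adora2a and the striatum and cortex median read -0.0178 and oxidative phosphorylation -0.0043 in tumor-bearing versus freely feeding, meninges -0.0844 in tumor-bearing versus food-restricted, and ribosomal proteins -0.0179 in food-restricted and -0.0032 in tumor-bearing versus freely feeding. Oxidative phosphorylation in tumor-bearing versus freely feeding also read -0.0108 with median centring, -0.0022 with the loop estimate, -0.0016 with the slide block, -0.0471 without replicate 2 and 0.0191 without replicate 1. Ribosomal proteins read -0.0179 with the slide block, -0.0029 without replicate 1 and -0.0077 without replicate 2 in food-restricted versus freely feeding, and -0.0403 without replicate 1 and 0.0419 without replicate 2 in tumor-bearing versus freely feeding. Orexigenic peptides read -0.0432 without replicate 1 and 0.2212 without replicate 2 in tumor-bearing versus food-restricted.

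Of the values of named genes over the settings, 1237 moved by less than 1 SD of the 2 arrays, 204 by more, and 7 reversed. Of the list medians the counts were 1663, 90 and 14. The reversals counted were all in genes past the size rule or lists set apart in that comparison. Sign changes of other genes and lists are not among them. With the shared component removed, Ghsr read 0.14 against -0.22 and Hcrt -0.28 against 0.18 in food-restricted versus freely feeding. Aquantile scaling, no filter on background and no requirement on the third pool left the 3 counts at 5, 147 and 19. The background filter left out few genes, since at least 92.6% of the probes were marked well above background in each channel. Outlier marks removed 35.7%. The background mark does not show expression. Olfactory receptor probes had a median log2 intensity of 9.96. The probes used for Bcl11b (7.28), Adora2a (7.67), Gad1 (7.91), Drd1 (7.95), Gpr6 (8.33) and Akap12 (8.33) were dimmer than that. Some other named genes, such as Chp1 at 10.07, were brighter.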

Other observations

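The second striatal list was written before its values were seen, the other values in this part were chosen afterwards, and no explanation is offered for them.

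The second list of striatal neuron genes gave a median of 0.22 in tumor-bearing over food-restricted rats (percentile 100), 0.11 in tumor-bearing over freely feeding rats (percentile 99.14) and -0.05 in food-restricted over freely feeding rats (percentile 23.27). None of its 19 genes passed the size rule in these comparisons. Gng7, a G protein subunit, read 0.44 ± 0.11 and Foxp1, a transcription factor of striatal neurons, 0.37 ± 0.12 over food-restricted rats, and Kcnip2, a potassium channel partner, -0.16 ± 0.08. Through the third pool the list read -0.10 in food-restricted over freely feeding rats (percentile 1.11).

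By the third-pool route, some lists inside the central 95% by the direct route lay outside it. Interferon response and antigen presentation read -0.12 (percentile 0.76) and the circadian clock -0.15 (percentile 1.17) in tumor-bearing over food-restricted rats. Cholesterol synthesis read -0.10 (percentile 0.69) and meninges -0.14 (percentile 1.59) in food-restricted over freely feeding rats, where oxidative phosphorylation read 0.03 (percentile 98.02).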
